A study of Homo sapiens with 12 samples.

How the data were processed

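Gene expression of the human melanoma cell line WM35 was measured on 12 Illumina 1-colour BeadChip arrays, which were positions of 1 BeadChip. Per the labels' protocols, RNA was extracted with TRIzol and a column, and 300 ng was labelled with biotin. Groups and replicate numbers were taken from the labels, which name the drug and the time but give no time for the vehicle arrays, so the same 2 control arrays served both times. The labels do not say that replicates were separate cultures, so the spread between replicates may be technical.

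The scanner table held a signal per probe as a linear intensity, exported by the authors from GenomeStudio per the submitters' processing notes, with the version not given in the sources used here. These deposited intensities had been background-subtracted, since 27.3% to 29.3% of the values on an array were below 0. The same deposited table gave a detection p-value per probe and array, per the file headers, and its steps imply 770 negative control bead types. The mean signal per array was 314.62 to 415.44, and 41.3% to 43.5% of 47230 probes were detected at a detection p under 0.05. The number of arrays limits the precision of every comparison.

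A processed table deposited by the authors held linear intensities of 38223 of these probes, and 9007 scanner probes were not in it. The columns were matched to arrays by sample label. Each column correlated by rank at 0.969 to 0.978 with the signal of its own array and at 0.919 or less with any other array. After centring each probe over the arrays, the correlation of the same array was at least 0.968 over the 6147 probes above a signal of 200 on all arrays. The column medians were 24.3 and 24.4 for the controls, 25.2, 25.0 and 24.0 for TFT 8 h, 24.2 and 25.0 for TFT 24 h, 24.7, 24.5 and 24.5 for LTM 8 h, and 23.8 and 23.5 for LTM 24 h. The scale was linear and genes were not centred, while the background correction, the normalization method and the choice of probes stay unknown. This table served only as an alternative.

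Signals were background-corrected with limma's neqc, which took the background from the detection p-values, with an offset of 16, quantile normalization between arrays and a log2 scale. Probes were kept if detected on at least 2 arrays, which left 24325. In the probe-gene table, 27004 processed-table probes had 1 gene symbol and 4 had several, and 11215 were not listed there and are unnamed here. Of the probes with 1 symbol, 26970 matched the RefSeq gene table of GRCh38.p14 by Entrez identifier, and 0 symbols needed an update. After the filter 15954 probes had 1 symbol and 8371 had none. Each gene was represented by its probe of highest mean intensity, giving 12131 genes, 3007 of them with more than 1 passing probe. The other probes of the named genes were each tested alone. Of 27 such tests for genes called on 12 arrays, 25 had the same sign and 2 the opposite sign, and on 9 arrays the numbers were 77, 73 and 4. Of these tests, 6 on 12 arrays and 28 on 9 arrays did not pass.

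All 12 arrays entered 1 limma fit of group means (lmFit and eBayes, moderated two-sided test, 7 residual degrees of freedom), with Benjamini-Hochberg adjustment over genes within each comparison and a threshold of 0.05. Counts were also taken at an absolute log2 fold change of at least 1. Comparisons were each drug with control at each time, LTM with TFT at each time, 24 h with 8 h for each drug, and the difference of the drugs in that change. The test, groups, gene lists, named-gene rule and all alternatives except those listed next were fixed before the data were examined. Alternatives chosen after seeing the data were the fit of 9 arrays without those labelled TFT 8 h replicate 3, TFT 24 h replicate 1 and LTM 8 h replicate 1 (4 residual degrees of freedom), a crossed pairing of replicate numbers, and the sign of list medians under other scalings in the fit of 9 arrays.

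A gene was not above background in a group if its detection p was 0.05 or more on every array of the group. Its fold was then given as a lower bound, the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal detected and the probe's own signal. Genes were named by rule. For each drug against control these were the 8 largest rises and 8 largest falls past the threshold with all treated arrays on 1 side of the controls, up to 4 members of each list that passed camera and of 7 lists followed throughout, and 14 fixed genes. Of the fixed genes 13 were measured, and TYR was not. For the other comparisons the rule took the 5 largest rises and 5 largest falls with arrays not overlapping, and 0 clone-type names were passed over. FOS and GDF15 on single arrays were named after their values were seen.

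The 31 gene lists covered p53 targets, DNA replication, mitosis, histone genes, nucleotide metabolism, DNA damage repair, the ATF4 response, aminoacyl-tRNA synthetases, ER chaperones, immediate early genes, NF-kB targets, the interferon response, snoRNA host genes, ribosomal proteins, ribosome biogenesis, translation factors, heat shock, proteasome, cholesterol synthesis, melanocyte lineage, the MITF-low state, MAPK output, apoptosis regulators, NRF2 and metallothionein genes, hypoxia and glycolysis, lysosome and autophagy, oxidative phosphorylation, and markers of fibroblasts, keratinocytes, leukocytes and endothelium. Lists could share genes, so their calls are not independent. DUSP5, EGR1, FOSL1, IER3, MAFF, MYC and PHLDA1, for example, were in both the immediate early and the MAPK output lists. ATF3 was in both the ATF4 response and the immediate early lists. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over lists. Alternatives were camera with a correlation estimated per list and fry. With an estimated correlation, camera's test has only the residual degrees of freedom of the fit, 7 or 4 here. A list that does not pass it is therefore not shown to be unchanged.

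Other alternatives were normexp with an offset of 50, median scaling, the authors' processed values, no detection filter, detection at 0.01 on every array of a group, every probe on its own, only the arrays compared, the replicate number as a block, eBayes with a trend and robust settings, and leaving out each array in turn. Whether replicate numbers paired arrays was checked from the correlation of same-numbered arrays' deviations from their group means. Shared controls were simulated with 100 draws of unchanged groups.

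The procedure was tested on simulated data with 12131 genes, 200 of them changed. With the spread of the 12 arrays, the comparison of LTM 24 h with control called 2% of genes changed by 0.5 on the log2 scale, 46% at 1, 98% at 2 and 100% at 4. The comparison of TFT 8 h with control called 4%, 60%, 98% and 100%. With the spread of the 9 arrays it called 42% at 0.5 and 100% at 1, 2 and 4. A shifted gene list was recovered and 0 of 29 unchanged lists were called. For TFT 8 h with the spread of the 12 arrays, the shifted list had a camera adjusted p of 3.35e-26 at the preset correlation. With an estimated correlation it was 0.000146. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated. False calls made up 4.26% to 9.4% of the calls in the simulated comparisons. The work used R 4.3.3, limma 3.58.1, Python 3.11.15 and matplotlib 3.10.9.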

Results

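Gene expression was measured on 12 Illumina 1-colour BeadChip arrays, all on 1 chip, in WM35, an established human melanoma cell line. According to the labels, 2 arrays held cells given the vehicle DMSO, with no time stated. The remaining arrays held cells given trifluridine (TFT, a thymidine analog that is incorporated into DNA) for 8 h on 3 arrays and for 24 h on 2 arrays, or lactimidomycin (LTM, an inhibitor of the elongation step of translation) for 8 h on 3 arrays and for 24 h on 2 arrays. Each drug was used at its 75% inhibitory concentration, which had been determined after 72 h of treatment. Between 19485 and 20551 of the 47230 probes were detected on an array, and 12131 named genes entered the tests. The study was set up to derive an expression signature of each drug, for later testing against outcome in melanoma patients. Nothing in the labels says whether replicates came from separate cultures, so the p-values measure only the spread between these samples, and the number of arrays limits their precision.

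The profiles of 3 arrays went against their labels. After centring each gene on its mean over the 12 arrays, the array labelled TFT 8 h replicate 3 correlated over genes at r = -0.53 and -0.52 with the other arrays of its label, but at 0.80 and 0.77 with LTM 8 h replicates 2 and 3. The array labelled LTM 8 h replicate 1 correlated at -0.51 and -0.43 with the other arrays of its label, and at 0.82 with TFT 24 h replicate 2. The array labelled TFT 24 h replicate 1 correlated at 0.48 with the other array of its label, and at 0.74 with each of TFT 8 h replicates 1 and 2. Among the remaining 9 arrays, arrays of the same label correlated at 0.76 to 0.93. Genes are not independent replicates, so these coefficients describe the arrays and carry no test. The same 3 arrays stood apart gene by gene. FOS, an immediate early transcription factor, had a log2 intensity of 10.37 on the array labelled TFT 8 h replicate 3, against 6.22 and 6.37 on the other TFT 8 h arrays and 10.32 and 10.09 on LTM 8 h replicates 2 and 3. GDF15, a secreted p53-responsive stress factor, was at 8.17 on the array labelled LTM 8 h replicate 1 and at 8.34 on TFT 24 h replicate 2, and between 5.03 and 6.15 on the other 10 arrays. All comparisons below used the groups as labelled. Each was repeated on 9 arrays without these 3, an alternative chosen after the data had been seen, whose p-values do not allow for that choice. With 9 arrays the TFT 24 h group holds 1 array, which is then assumed to vary like the other groups.

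**Figure D1:**
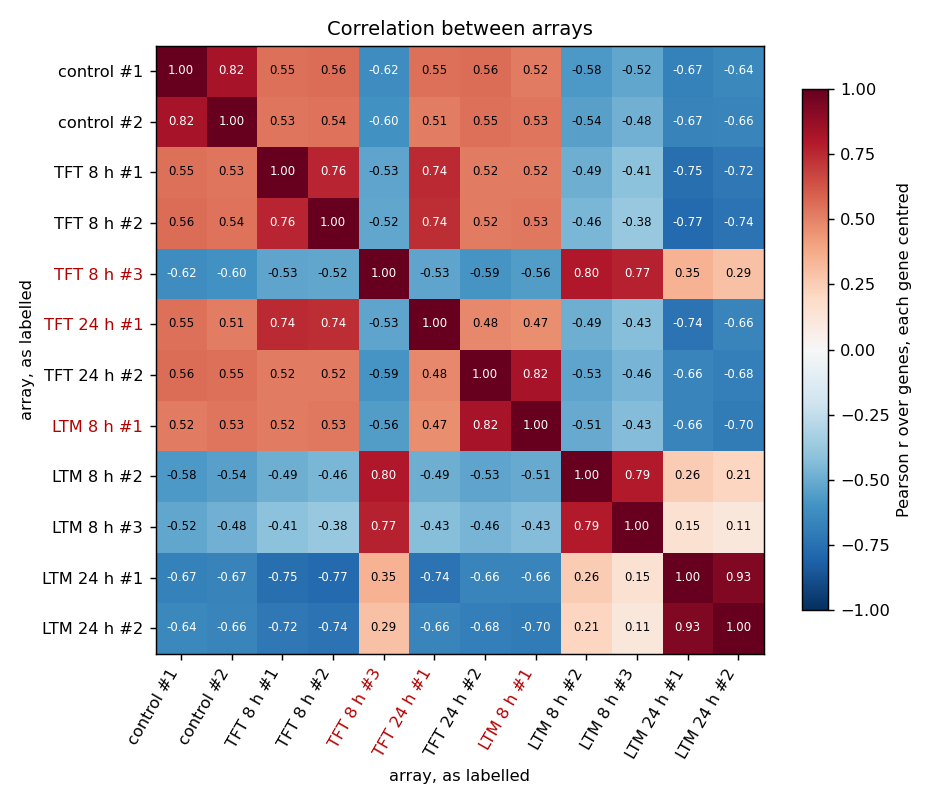
Pearson correlation over 12131 genes between each pair of the 12 arrays, with each gene centred on its mean, in the order and with the names of the labels. The 3 arrays in red type correlate more closely with another group (0.74 to 0.82) than with the rest of their own.

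LTM for 24 h gave the largest number of changed genes against control. Neither group of this comparison contains any of the 3 arrays, so its log2 fold changes do not depend on them. Its SEs, adjusted p-values and counts do, because the fit pools the spread within all groups. The median SE over genes for this comparison was 0.22 as labelled and 0.14 without the 3 arrays. With limma and Benjamini-Hochberg adjustment, 2887 of 12131 genes rose and 2866 fell at an adjusted p under 0.05. Of these, 1650 and 1617 changed by at least 1 on the log2 scale. List members counted as changed below are to be read against the 2887 and 2866. Among the genes with the largest rises were FOS (log2 fold change 4.88, SE 1.28, adjusted p = 0.00956), the stress-induced transcription factor ATF3 (4.43, SE 0.74, adjusted p = 0.000885), the natriuretic peptide precursor NPPB (4.74, SE 0.84, adjusted p = 0.00124) and TNFAIP3, which encodes the ubiquitin-editing enzyme A20 (4.30, SE 1.32, adjusted p = 0.0205). NPPB and TNFAIP3 were detected on only 1 of the 2 control arrays. Their control means of 4.96 and 4.85 lay near the lowest signals detected there (4.93 and 4.91), so background limits the size of these rises. The histone gene H2AC6 rose from 6.17 ± 0.14 (SD, n = 2) to 10.56 ± 0.34 (SD, n = 2). The histone gene H4C8, RUNDC3B and PSG4, a pregnancy-specific glycoprotein, were not well above background on either control array and were at least 32.2-fold, 19.8-fold and 18.3-fold higher, with adjusted p = 0.00059, 2.37e-07 and 1.51e-06. Such bounds set the brighter group's mean against the lowest signal detected on each array of the dimmer group, or against the probe's own signal where that was higher. The largest falls were in TMEM160 (-3.16, SE 0.38, adjusted p = 0.000166), NRGN (-2.99), the long noncoding RNA SLCO4A1-AS1 (-2.97), NME3 (-2.85), the mitochondrial protein gene CHCHD10 (-2.84), the intermediate filament gene NES (-2.76) and, by 1 probe, ANKRD9 (-2.76), whose other probe fell less (-0.69, adjusted p = 0.0161). MXD3, a MAX-binding repressor, was not above background on either treated array and was at least 6.51-fold lower. Leaving out LTM 24 h replicate 2 lowered the number of changed genes from 5753 to 3725, and leaving out control replicate 2 lowered it to 3826. With only the control and LTM 24 h arrays in the fit it was 7374, and without the 3 arrays it was 7701. All 5753 genes were among the 7701. The log2 fold changes of this comparison are the same in both fits, so the same sign carries no information.

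Of 18 aminoacyl-tRNA synthetases measured, 16 rose and 0 fell after LTM for 24 h (16 adjusted over the list alone), with a median log2 fold change of 1.15 and a camera adjusted p of 5.99e-08. The leading members were LARS1 (2.42, SE 0.17, adjusted p = 1.91e-05), IARS1 (2.09), TARS1 (1.94) and GARS1 (1.84), while another IARS1 probe rose less (0.57, adjusted p = 0.00717). Of 38 genes of the ATF4 response, 22 rose and 3 fell (23 and 3 adjusted over the list alone), with a median of 0.82 and a camera adjusted p of 0.000152. Its largest changes were in ATF3, CTH, which makes cysteine from cystathionine (4.28, SE 0.59), DDIT3, which encodes CHOP (3.69, SE 0.66), and PPP1R15A, which encodes GADD34 (3.24, SE 0.86). ATF4 itself rose by the probe used (1.89, SE 0.55, adjusted p = 0.0155), and of its 2 other probes 1 rose (2.05, adjusted p = 0.0193) and 1 did not pass (-0.02, adjusted p = 0.96). Among 37 translation factors, 18 rose and 3 fell (18 and 3 adjusted over the list alone; median 0.39, camera adjusted p = 0.0115), led by EIF4A2 (2.55), EIF3D (1.52), EIF4G2 (1.37) and EIF3J (1.36). Of 45 ribosome biogenesis genes, 25 rose and 4 fell (27 and 4 adjusted over the list alone; median 0.87, camera adjusted p = 0.000441), with UTP14A at 2.21, RRN3 at 1.79 and DDX10 at 1.67. With an estimated correlation in place of the preset one, these 4 lists had adjusted p = 0.531, 0.603, 0.603 and 0.818, and none of the 12 lists that camera called for LTM at 24 h passed. The correlation was estimated from the residuals of all 12 arrays, so the 3 arrays enter it. Without them, too, no list that camera called for LTM at 24 h passed with an estimated correlation. That version of camera has few degrees of freedom, here and below, so not passing does not show that a list was unchanged.

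Some immediate early, NF-kB, p53 and histone genes rose in the same comparison, and their lists had adjusted p = 0.832, 0.818, 0.818 and 0.818 with an estimated correlation. Over both directions, changed members were about as common among the immediate early genes as among all 12131 genes, where 5753 changed. Of 44 immediate early genes, 17 rose and 4 fell (17 and 4 adjusted over the list alone; median 1.02, camera adjusted p = 0.022), among them EGR1 (3.89, SE 0.75) and KLF10 (3.72, SE 0.98; another probe 1.29, adjusted p = 0.00138). Of 25 NF-kB targets, 12 rose and 2 fell (12 and 2 adjusted over the list alone; median 1.25, camera adjusted p = 0.0203), including NFKB2 (3.05), RELB (2.93) and IL1A (2.63). Of 39 p53 targets, 19 rose and 2 fell (19 and 2 adjusted over the list alone; median 0.77, camera adjusted p = 0.00235). The largest were GADD45A (3.03, SE 0.90, adjusted p = 0.0177), PMAIP1, which encodes NOXA (2.89), the ribonucleotide reductase subunit RRM2B (2.51) and the p53 ubiquitin ligase MDM2 (2.29). MDM2 was detected on only 1 of the 2 control arrays. CDKN1A, which encodes p21, was not above background on the control arrays or on 1 of the 2 treated arrays, and with a bound of at least 1.05-fold did not pass (adjusted p = 0.575). Of 22 histone genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; median 0.82, camera adjusted p = 0.000891), with H4C14 at 4.17 and H2BC5 at 3.35 (another probe 2.19, adjusted p = 0.0079). Histone genes are near-identical copies, so a probe can read more than 1 of them. Of 16 snoRNA host genes, 8 rose and 2 fell (9 and 2 adjusted over the list alone), with TAF1D at 3.11, SNHG15 at 2.69, ZFAS1 at 1.92 and SNHG12 at 1.73, but the list did not pass camera (median 1.36, adjusted p = 0.0764). Fry, which tests a list without setting it against other genes, called 13 of the 30 lists in this comparison as labelled and 23 without the 3 arrays. As labelled it did not call the ribosome biogenesis, NF-kB and immediate early lists (adjusted p = 0.052, 0.063 and 0.192).

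Members of the DNA replication, mitosis, oxidative phosphorylation and ribosomal protein lists fell after LTM for 24 h, and the lists had adjusted p = 0.603, 0.818, 0.818 and 0.603 with an estimated correlation. Of 47 DNA replication genes, 31 fell and 1 rose (31 and 2 adjusted over the list alone; median -0.87, camera adjusted p = 2.39e-06), led by E2F2 (-2.20, SE 0.29), GINS2 (-2.05), POLD1 (-2.01) and RNASEH2A (-1.75). Thymidylate synthase TYMS (-1.60, SE 0.20, adjusted p = 0.000212) and thymidine kinase TK1 (-1.41, SE 0.21, adjusted p = 0.000552) were lower too. Of 47 mitosis genes, 18 fell and 1 rose (15 and 0 adjusted over the list alone; median -0.47, camera adjusted p = 0.0005), with CDCA3 at -2.24, CDC25C at -1.76, AURKB at -1.72 and UBE2C at -1.72. The other CDC25C probes did not pass (-0.76 and -0.57, adjusted p = 0.137 and 0.294). Cyclin B1, CCNB1, was at -1.05 (SE 0.36, adjusted p = 0.0359). Over both directions, the changed share of the mitosis list was below that of all genes (5753 of 12131), but its changes were nearly all falls. Of 39 oxidative phosphorylation genes, 24 fell and 2 rose (26 and 2 adjusted over the list alone; median -0.77, camera adjusted p = 1.93e-06), including NDUFB10 (-2.17), ATP5F1D (-1.79) and NDUFC1 (-1.65). UQCRB fell by 1 probe (-1.77), and its other probes gave -0.21 and 0.17 with adjusted p = 0.379 and 0.476. Of 66 ribosomal protein genes, 30 fell and 2 rose (30 and 2 adjusted over the list alone; median -0.37, camera adjusted p = 0.000274), with RPL29 at -1.75 and RPS28 at -1.67. The melanocyte lineage list did not move as a set (median -0.09, camera adjusted p = 0.957). Within it the receptor genes ERBB3 (-2.62, other probes -1.95 and -0.95) and EDNRB (-1.37) and the transcription factor SOX10 (-1.02) fell, and MITF rose (1.48, SE 0.29, adjusted p = 0.00225). GAPDH was at 0.03 (adjusted p = 0.873) and ACTB at -0.14 (adjusted p = 0.511), while another ACTB probe gave 0.61 with an adjusted p of 0.0396.

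**Figure D2:**
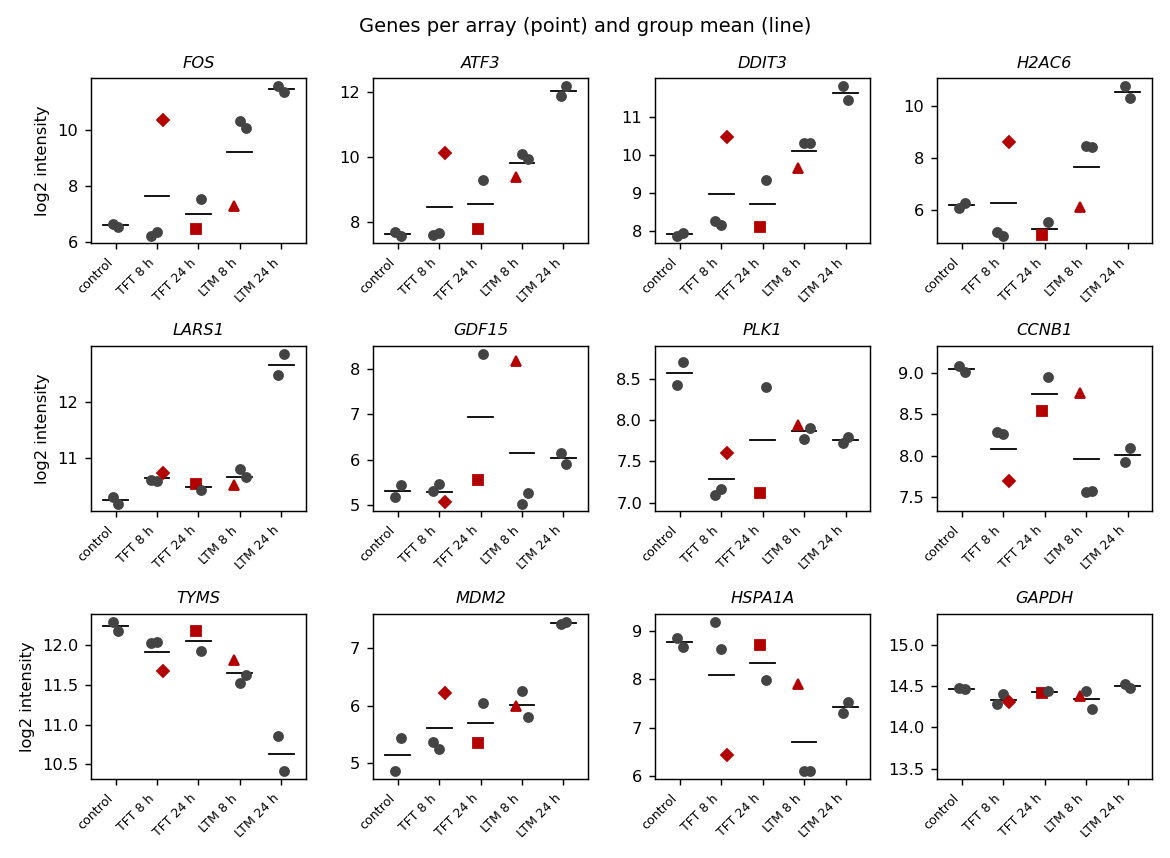
Normalized log2 intensity of 12 genes on each array, by labelled group, with the group mean as a line; each axis has its own range and does not start at 0. Red symbols mark the arrays labelled TFT 8 h replicate 3 (diamond), TFT 24 h replicate 1 (square) and LTM 8 h replicate 1 (triangle), which lie near arrays of another group for FOS, GDF15 and HSPA1A.

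LTM for 8 h gave 0 genes past the threshold against control on all 12 arrays with limma. At an unadjusted p under 0.05 there were 1937 genes, where 607 would be expected by chance, and a trended and robust version of the same test also called 0. Leaving out the array labelled LTM 8 h replicate 1 alone raised the number to 1291. On 9 arrays, 2290 genes rose and 2295 fell, and 601 and 316 of these changed by at least 1 on the log2 scale. As labelled, the log2 fold changes of ATF3 and DDIT3 were 2.19 (SE 0.67, adjusted p = 0.242) and 2.16 (SE 0.60, adjusted p = 0.234). With 9 arrays they were 2.39 (SE 0.13, adjusted p = 2.86e-06) and 2.38 (SE 0.14, adjusted p = 4.09e-06).

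In the fit of 9 arrays, the genes that rose most after LTM for 8 h were TNFAIP3 (3.86), the metalloprotease gene ADAMTS6 (3.69), the cytokine LIF (3.63, SE 0.11), FOS (3.61, SE 0.14), the kinase NUAK2 (3.53), RGS2 (3.44), IL24 (3.41) and LINC01119 (3.27). TNFAIP3 was detected on only 1 of the 2 control arrays, which are the same as at 24 h. The genes that fell most were the secreted ligand WNT5A, which was not above background on the treated arrays and at least 5.90-fold lower, KCNS3 (-2.76), the heat shock gene HSPA1A (-2.66), LRFN3 (-2.52), ERBB3 (-2.48), the collagen COL5A2 (-2.45), the Wnt-binding SFRP1 (-2.28) and CHST1, at least 4.25-fold lower. Of the other ERBB3 probes, 1 fell less (-0.66, adjusted p = 0.00658) and 1 did not pass (-0.41, adjusted p = 0.118). Of 44 immediate early genes, 31 rose and 3 fell (32 and 3 adjusted over the list alone; median 1.12, camera adjusted p = 1.06e-12), including FOSB (2.84), EGR1 (2.82) and DUSP1 (2.72). Of 25 NF-kB targets, 18 rose and 2 fell (18 and 3 adjusted over the list alone; median 1.35), with the chemokine CCL2 at 3.03 and IL1A at 2.75. Of 45 ribosome biogenesis genes, 31 rose and 0 fell (32 and 0 adjusted over the list alone; median 0.60), led by POLR1C (1.27), NOP16 (1.23) and RRS1 (1.16). Of 16 snoRNA host genes, 12 rose and 2 fell (12 and 2 adjusted over the list alone; median 0.99), with SNHG15 at 1.79 and ZFAS1 at 1.54. The ATF4 response (17 rose, 3 fell; 17 and 5 adjusted over the list alone), MAPK output (13 rose, 1 fell; 14 and 1 adjusted over the list alone), histone genes (12 rose, 1 fell; 12 and 1 adjusted over the list alone) and the MITF-low state (15 rose, 3 fell; 15 and 3 adjusted over the list alone) were also called up, with PPP1R15A at 2.47, MYC at 2.01, DUSP5 at 2.68 and NRG1 at 2.64 (another probe 0.74, adjusted p = 0.00524). MYC and DUSP5 are also members of the immediate early list. Of 47 mitosis genes, 38 fell and 0 rose (39 and 0 adjusted over the list alone; median -0.62, camera adjusted p = 1.06e-12), including PBK (-1.57), CCNB1 (-1.48) and KIF20A (-1.44). DNA replication (15 fell, 2 rose; 15 and 2 adjusted over the list alone), with CCNE1 at -1.02 and PCNA at -0.90, and heat shock genes (12 fell, 3 rose; 16 and 3 adjusted over the list alone), with HSPA1B at -1.56 and BAG3 at -0.98, were called down. HSPA1A and HSPA1B are near-identical copies whose probes can read both. The estimated correlation left none of the 11 lists called, with adjusted p from 0.126 to 0.279. As labelled, on 12 arrays, camera called 11 lists for LTM at 8 h, 10 of them in common with the 9-array fit. The p53 targets had a camera adjusted p of 0.000683 with 12 arrays and 0.0506 with 9, and the histone genes passed with 9 arrays (adjusted p = 0.00108). The estimated correlation gave adjusted p from 0.719 to 0.779 for the 11 lists called on 12 arrays.

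TFT for 8 h gave 0 genes past the threshold against control on all 12 arrays, with 1123 at an unadjusted p under 0.05 and 0 in the trended and robust version. As labelled, camera called the mitosis list lower, with a median of -0.58 over 47 genes and an adjusted p of 5.53e-26. No member passed over all genes and 25 fell adjusted over the list alone, and the estimated correlation gave an adjusted p of 0.455. Camera also called the ribosome biogenesis, immediate early, MITF-low state and NF-kB lists higher, with adjusted p from 0.455 to 0.962 under the estimated correlation, and the array labelled TFT 8 h replicate 3 was the one with FOS at 10.37. On 9 arrays, 226 genes rose and 190 fell, and 26 and 17 of these changed by at least 1 on the log2 scale. The mitosis list stayed lower (median -0.51, camera adjusted p = 2.08e-25; 18 fell and 0 rose, 37 and 0 adjusted over the list alone; adjusted p = 0.244 with an estimated correlation). Its largest falls were in the mitotic kinase PLK1, from 8.56 ± 0.19 (SD, n = 2) to 7.12 ± 0.05 (SD, n = 2) with an adjusted p of 0.00189, the kinesin KIF20A (-1.28), the centromeric histone CENPA (-1.15) and DLGAP5 (-1.07). CCNB1 was at -0.78 (SE 0.12, adjusted p = 0.0122).

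Other genes that changed after TFT for 8 h in the fit of 9 arrays were led by GLIPR1 (1.85, SE 0.19), ANKRD1, a target of YAP signalling (1.81, SE 0.12, adjusted p = 0.000321), CPA4 (1.73), the semaphorin receptor PLXNA2 (1.70), ANGPTL4 (2.83-fold, adjusted p = 0.00189), the potassium channel KCNH1 (1.48), EPHB1 (1.33) and SCRG1 (1.28). The largest falls outside mitosis were in MXD3 (-1.92, SE 0.13, adjusted p = 0.000321), TYMSOS (-1.24), SLCO4A1-AS1 (-1.16), GGACT (-1.14) and TEF, which was not above background on the treated arrays and at least 2.17-fold lower. Histone genes were called lower (4 of 22 fell, 7 adjusted over the list alone), with H2AC6 at -1.11 and H2AX at -0.67, and the MITF-low state higher (5 of 30 rose, 10 adjusted over the list alone), with CXCL8 at 0.83 and THBS1 at 0.76. ER chaperones (3 of 26 rose, 4 adjusted over the list alone; HSPA5 0.71, CALR 0.65), ribosome biogenesis (3 of 45 rose, 5 adjusted over the list alone; NOP16 0.67) and immediate early genes (6 rose and 1 fell of 44, 10 and 3 adjusted over the list alone; DUSP5 1.12, JUN 1.08) were called higher, with medians of 0.16, 0.17 and 0.17 that turned to -0.02, -0.03 and -0.01 under median scaling, which moved the median of all genes by -0.16. With the estimated correlation these 5 lists had adjusted p from 0.316 to 0.435. The p53 targets did not move as a set (median 0.06, camera adjusted p = 0.8). CDC25A (0.73) and CCNE1 (0.59) rose, and TYMS (-0.21, adjusted p = 0.485), TK1 (-0.06, adjusted p = 0.849), MDM2 (0.15, adjusted p = 0.715) and ATF3 (-0.00, adjusted p = 0.994) did not pass. Another probe of PLXNA2 (0.57, adjusted p = 0.0659), of ANGPTL4 (0.02, adjusted p = 0.958), of NOP16 (0.57, adjusted p = 0.0659) and of CDC25A (0.46, adjusted p = 0.123) did not pass either.

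TFT for 24 h gave 0 genes past the threshold on all 12 arrays, with 565 at an unadjusted p under 0.05, where 607 would be expected by chance, and 0 in the trended and robust version. As labelled, camera called the p53 targets higher (median 0.36, adjusted p = 3.35e-05) and the mitosis genes lower (median -0.38, adjusted p = 3.16e-16), with no member of either past the threshold over all genes or adjusted over the list alone. Both had an adjusted p of 0.51 with an estimated correlation. The MITF-low state list was also called higher and the histone and DNA replication lists lower (medians 0.26, -0.31 and -0.11), with adjusted p from 0.51 to 0.971 under the estimated correlation. Without TFT 24 h replicate 2 the median of the DNA replication list turned to 0.04.

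With 9 arrays, the comparison at 24 h sets the single array TFT 24 h replicate 2 against the controls, and 134 genes were higher and 24 lower on it. GDF15 was higher by 3.03 (SE 0.18, adjusted p = 0.000263), followed by the carboxypeptidase CPA4 (2.36), LRRC17 (2.02), the cyclooxygenase PTGS2 (1.79), GLIPR1 (1.69), ATF3 (1.68, SE 0.16, adjusted p = 0.00536), IL24 (1.68) and IFI30 (1.67). Of 39 p53 targets, 7 were higher and 0 lower (22 and 0 adjusted over the list alone; median 0.57, camera adjusted p = 3.98e-14, adjusted p = 0.0678 with an estimated correlation), including SESN2 (1.27), TP53INP1 (1.23) and the nucleotide excision repair gene DDB2 (1.20). CDKN1A was not above background on the controls and was at least 1.83-fold higher (adjusted p = 0.0169), while MDM2 was at 0.90 (adjusted p = 0.113) and RRM2B at 0.75 (adjusted p = 0.192). Of 38 ATF4 response genes, 5 were higher (11 adjusted over the list alone; adjusted p = 0.103 with an estimated correlation), among them DDIT3 (1.42) and PCK2 (0.89), and 4 of 25 NF-kB targets were higher (6 adjusted over the list alone; adjusted p = 0.3 with an estimated correlation), among them PTGS2 (1.79) and CCL2 (1.48). Of 47 DNA replication genes, 2 were lower (8 adjusted over the list alone; median -0.24, adjusted p = 0.103 with an estimated correlation), namely MCM6 (-0.86) and MCM5 (-0.82). The largest falls included OPN3 (-1.20), EID2B (-1.11), PMEPA1 (-1.05), UBE2MP1 (-1.03), ICE1 (-1.03) and MXD3 (-0.96). Several of these genes rest on 1 probe, since another probe did not pass for LRRC17 (0.22, adjusted p = 0.689), PTGS2 (1.17, adjusted p = 0.0944), TP53INP1 (0.79, adjusted p = 0.117), PCK2 (0.61, adjusted p = 0.185), OPN3 (-0.14, adjusted p = 0.704) and PMEPA1 (-0.16, adjusted p = 0.766, while 1 more probe passed at -1.03, adjusted p = 0.0189). Camera also called the interferon response (median 0.31), fibroblast marker (0.56), endothelial marker (0.31) and MITF-low state (0.14) lists higher and the mitosis (-0.20) and histone (-0.17) lists lower, with adjusted p from 0.3 to 0.369 under the estimated correlation. Only 9 of 15 fibroblast markers and 5 of 13 endothelial markers were measured, so those medians rest on few genes and on 1 TFT array. The immediate early list was called higher with a median of -0.00 and a mean of 0.18, and its median was 0.01 with a normexp offset of 50 and 0.05 with the authors' values. Of its 44 genes, 5 were higher and 0 lower (11 and 3 adjusted over the list alone), with an adjusted p of 0.369 under the estimated correlation. TYMS was at -0.31 (adjusted p = 0.429) and TK1 at -0.17 (adjusted p = 0.68).

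**Figure D3:**
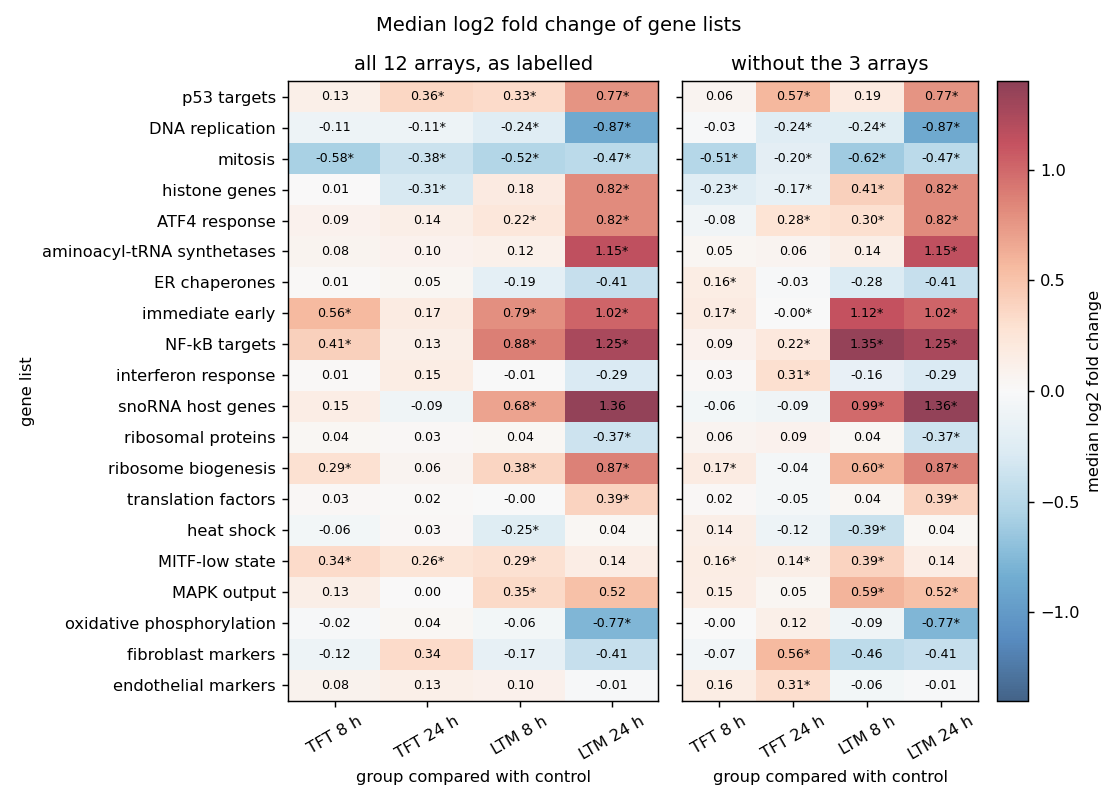
Median log2 fold change against control of each gene list that camera called in at least 1 of these comparisons, with all 12 arrays (left) and without the 3 arrays (right). An asterisk marks a camera adjusted p under 0.05 at the preset correlation. None of these calls held with an estimated correlation, a version with few degrees of freedom. The medians of the ER chaperone, immediate early and ribosome biogenesis lists at TFT 8 h on the right turned negative under median scaling.

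The drugs were compared directly at each time. At 8 h, LTM against TFT gave 0 genes on all 12 arrays with limma, 347 at an unadjusted p under 0.05, fewer than the 607 expected by chance, and 0 in the trended and robust version. Without the 3 arrays, 2171 genes were higher and 2085 lower after LTM, led upward by FOS (3.91), TNFAIP3 (3.71), H2AC6 (3.39), NUAK2 (3.32) and IL24 (3.17). Led downward were HSPA1A (-2.81), SFRP1 (-2.67), VSNL1 (-2.64), the hyaluronan synthase HAS2 and WNT5A, the last 2 at least 5.11-fold and 5.22-fold lower and not above background after LTM. Other probes of VSNL1 (-0.95, adjusted p = 0.00676) and HAS2 (-1.21, adjusted p = 0.00025) were lower by less. The mitosis list did not pass camera between the drugs at 8 h with 9 arrays (median -0.14, adjusted p = 0.235). As labelled their median was 0.08 (camera adjusted p = 0.0231) and turned to -0.01 under median scaling, where the median of all genes was -0.07. Camera called 10 lists between the drugs at 8 h as labelled, with 0 members past the threshold and adjusted p from 0.829 to 0.98 under the estimated correlation. At 24 h, 2789 genes were higher and 2980 lower after LTM than after TFT as labelled, and 5608 of these 5769 genes were among the 7201 called with the same sign without the 3 arrays. Leaving out LTM 24 h replicate 2 gave 3651. H2AC6 (5.28, SE 1.08), FOS (4.46) and H4C14 (4.25) were higher after LTM, as were H4C8, by at least 32.2-fold, and RUNDC3B, by at least 19.8-fold. FST, a binding protein of activin (-3.00, SE 0.51), the steroid-metabolizing AKR1C2 (-2.96), ECSCR (-2.93), CMTM8 (-2.91) and CHCHD10 (-2.89) were lower. Aminoacyl-tRNA synthetases (16 of 18 higher, 17 adjusted over the list alone; median 1.05) and oxidative phosphorylation genes (27 of 39 lower and 2 higher, 27 and 2 adjusted over the list alone; median -0.97) separated the drugs, with adjusted p = 0.548 and 0.732 under the estimated correlation. The p53 targets did not pass camera between the drugs at 24 h (median 0.16, adjusted p = 0.115).

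Between 8 h and 24 h of LTM, 2460 genes rose and 2428 fell as labelled, and 4850 of these 4888 genes were among the 6525 called with the same sign without the 3 arrays. Leaving out LTM 24 h replicate 2 gave 2767. RUNDC3B rose by at least 19.3-fold, and PSG4 (3.85), PLA2G4C (3.62), H4C8 (3.56) and TMEM45A (3.55) were the next largest. The chemokine CCL2 (-3.98, SE 0.64, adjusted p = 0.00079), SLCO4A1-AS1 (-2.80), NES (-2.54), TMEM160 (-2.51) and, by 1 probe, the Notch ligand DLL3 (-2.48) fell most, while another DLL3 probe gave -0.13 (adjusted p = 0.63). Of 18 aminoacyl-tRNA synthetases, 16 rose (17 adjusted over the list alone; median 1.07), and of 66 ribosomal protein genes, 33 fell and 2 rose (37 and 2 adjusted over the list alone; median -0.39), with adjusted p = 0.428 and 0.515 under the estimated correlation. Between 8 h and 24 h of TFT, 0 genes passed with limma as labelled, with 281 at an unadjusted p under 0.05 and 0 in the trended and robust version, and the 11 lists that camera called had adjusted p from 0.737 to 0.836 under the estimated correlation. Without the 3 arrays, 140 genes were higher and 50 lower on the 1 array at 24 h. GDF15 (2.95), LRRC17 (1.73), ELAPOR1 (1.70), ATF3 (1.68) and CABYR (1.68) led the rises, and EPHB1 (-1.83), BEND3 (-1.33) and PLXNA2 (-1.33) the falls, with KCNH1 and HHAT not above background at 24 h and at least 2.77-fold and 2.52-fold lower. Other probes did not pass for LRRC17 (0.30, adjusted p = 0.585), BEND3 (-0.22 and -0.12, adjusted p = 0.571 and 0.793) and PLXNA2 (-0.17, adjusted p = 0.691). In the same fit, p53 targets were higher at 24 h than at 8 h (9 of 39, 20 adjusted over the list alone; median 0.43), as were mitosis genes (6 of 47, 16 adjusted over the list alone; median 0.33), with adjusted p = 0.0546 and 0.156 under the estimated correlation.

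**Figure D4:**
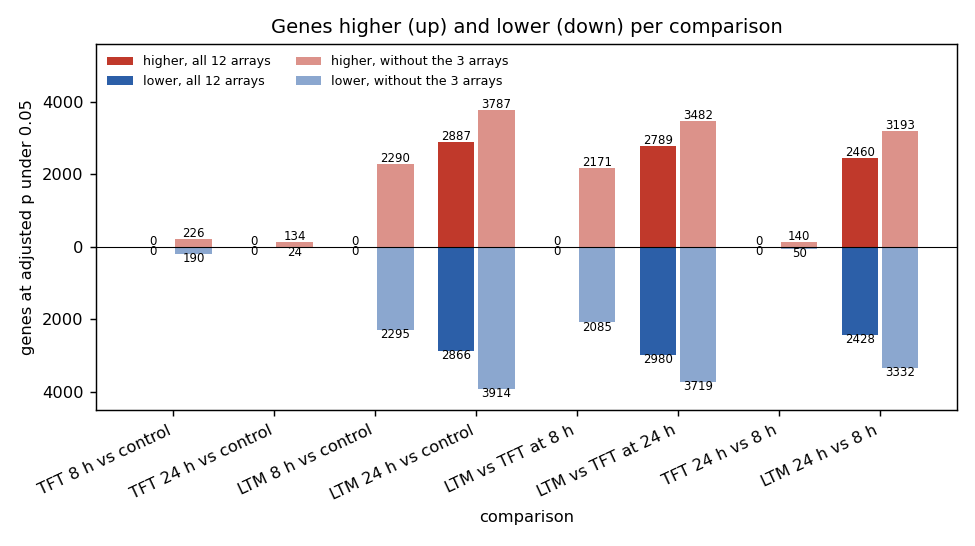
Number of genes higher (above 0) and lower (below 0) at an adjusted p under 0.05 in each comparison, with all 12 arrays as labelled (dark bars) and without the 3 arrays (pale bars). The 5 comparisons with 0 genes as labelled have 158 to 4585 without the 3 arrays.

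All 4 comparisons with control share the same 2 control arrays. With no calls in 3 of them as labelled, no gene was shared between comparisons. The log2 fold changes of TFT and LTM at 8 h correlated over genes at r = 0.83 as labelled, where unchanged groups simulated against the same controls gave 0.60, and their covariance was 0.111 against a simulated 0.0368. Without the 3 arrays the correlation was 0.34 against a simulated 0.50, and the covariance 0.0550 against 0.0119. At 24 h the drugs correlated at 0.16 against a simulated 0.50 as labelled (covariance 0.0396 against 0.0369), and at 0.09 against 0.41 without the 3 arrays (0.0275 against 0.0118). Between 8 h and 24 h the correlation was 0.63 against 0.55 for TFT (0.0505 against 0.0369) and 0.63 against 0.55 for LTM (0.259 against 0.0370) as labelled, and 0.43 against 0.41 (0.0379 against 0.0119) and 0.67 against 0.50 (0.375 against 0.0119) without the 3 arrays. Of the 9-array calls for LTM, 1711 genes rose and 1773 fell at both 8 h and 24 h, where independent lists would share 715 and 740, and 256 went opposite ways. For TFT, 35 rose and 9 fell at both times (2.50 and 0.376 for independent lists), and 1 went opposite ways. At 8 h, 136 genes rose and 122 fell after each drug (42.7 and 35.9 for independent lists), and 36 went opposite ways. At 24 h, 52 rose and 16 fell after each drug (41.8 and 7.74 for independent lists), and 46 went opposite ways. Unchanged groups simulated against the same controls shared 0.01 calls or fewer on average. With no gene changed almost none is called, so that number is no baseline for lists with many calls. The controls were not split, since each side would keep only 1 array, so part of the excess may come from sharing them.

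Of the 31 gene lists fixed in advance, 30 had at least 5 measured genes. The keratinocyte marker list had 1 and was not tested. The lists of nucleotide metabolism, DNA damage repair, melanocyte lineage, proteasome, cholesterol synthesis, apoptosis regulators, NRF2 and metallothionein genes, hypoxia and glycolysis, lysosome and autophagy, and leukocyte markers passed camera in no comparison with control, either on 12 or on 9 arrays.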

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

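The tests of moved labels, of a failed array and of the culture time of the controls, and every value from 9 arrays, were chosen only after the result was seen. The test of culture time is the last of 3 forms, after 1 on shared arrays and 1 on shares of calls (41.0% to 83.9%), which the number of calls limited.

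The change between 8 h and 24 h differed between LTM and TFT in 3439 genes by limma's test of the difference itself, and in 4558 without the 3 arrays whose profiles went against their labels, with 3174 shared at the same sign. Among fixed genes, the difference (LTM minus TFT) was 2.03 for RRM2B, 1.33 for MDM2, -1.15 for TYMS and -1.31 for TK1, and without the 3 arrays it was 1.63, 0.66 (adjusted p = 0.134), -0.82 and -0.96. The lists that differed had medians of 0.999 for aminoacyl-tRNA synthetases, 1.03 for histone genes, 0.74 for ribosome biogenesis, 0.50 for translation factors, 0.42 for the ATF4 response, -0.94 for oxidative phosphorylation, -0.75 for DNA replication and -0.35 for ribosomal proteins. None of these 8 lists passed with an estimated correlation (adjusted p from 0.479 to 0.834). The ATF4 response was not called without the 3 arrays. Signal also lay outside the named genes, since 2708 of 8371 probes without a gene name here changed after LTM for 24 h against control.

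The arrays labelled TFT 8 h replicate 3, TFT 24 h replicate 1 and LTM 8 h replicate 1 resembled another group more than their own. A failed array is argued against by the lowest of their highest correlations with another array, 0.744. Mixing of RNA from the own label and the resembled group is argued against for TFT 8 h replicate 3 and LTM 8 h replicate 1. Their positions between own label (0) and resembled array (1) were 1.05 and 0.986. For TFT 24 h replicate 1, at 0.987, the genes were chosen with the doubted LTM 8 h replicate 1. That position assumes moved labels and decides nothing. Mixing with other samples was not tested. Labels moved around among these groups may account for the pattern, because each of the 3 correlated with the remaining arrays of the group it resembles at 0.738 or more and moving all 3 would keep the group sizes. The 3 arrays were chosen for resembling another group, so these correlations restate the pattern and are no separate evidence. The lowest, 0.738, was under the lowest between remaining arrays of the same label, 0.764. The labels were kept, and whether the move happened before or after hybridization, or whether the cultures themselves differed, stays open.

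For LTM against TFT at 8 h, the 6 arrays make only 10 splits, too few for a share under 0.05. The labelled split gave 0 genes, so all 10 splits gave as many, and the highest other gave 4975. With 0 genes every split meets that mark, so the count carries no information. The highest split sets TFT 8 h replicates 1 and 2 with LTM 8 h replicate 1 against the rest, a structure of the samples already seen in the correlations and no separate evidence.

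The 5753 genes changed after LTM for 24 h are argued not to come from the choice of quantile normalization as the whole cause, since median scaling gave 5343. Both scalings bring the arrays to a common level, so this cannot tell whether a shift in the whole signal was removed. The mean signal before scaling was 415 and 403 on the controls and 340 and 315 on the LTM 24 h arrays. Fewer detected probes are argued against, since the LTM 24 h arrays detected at least 20218. A difference in culture time from the controls, whose time is not given, is argued against as the whole cause and stays open as a part of it. The genes changed in 1 LTM 24 h array against control had a median change of 79.5% to 108% of that size, in the same direction, in the other LTM 24 h array against TFT at 24 h, with both TFT arrays or either of them. TFT 24 h replicate 1 resembled TFT 8 h, so runs that include it may not test a culture time of 24 h. With TFT 24 h replicate 2 alone the values were 107% and 82.2%, each resting on that 1 TFT array. A response to the drug is a hypothesis that stays open, untested apart from the groups themselves.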

How the results depend on the processing

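The fit without the 3 arrays and the crossed pairing were chosen only after the data were seen. All 97 calls of named genes kept their direction and side of the threshold under normexp, median scaling, the authors' values, the stricter detection filter, only the groups compared, the trended test and the fit without the 3 arrays, and 95 did with no detection filter. Directions could not change under the trended test or with only the groups compared. Nor could they without the 3 arrays for LTM 24 h against control, where neither group lost an array. Leaving out 1 array kept 350 of 401 gene calls and weakened 51, and for lists kept 350 of 410, weakened 56 and reversed 4. An estimated correlation, with its few degrees of freedom, ended all 77 list calls, and fry kept 27. Fry called 0 of 30 lists for LTM 8 h and for TFT 8 h against control as labelled. Without the 3 arrays it called 22 and 10. The replicate block weakened 10 of the 77, median scaling 7, the authors' values 3 and the stricter detection filter 2. The fit without the 3 arrays weakened 7 and reversed 4. The cause was not tested for any change below, apart from the fewer arrays or other units tested that the alternative itself brings. Dim genes near background, such as CDKN1A, are limited by signal over background.

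For LTM 8 h against control the count of 0 became 1 with median scaling and 2 with no detection filter. Every probe on its own gave 9952 probes for LTM 24 h, 9775 for LTM against TFT at 24 h, 8119 for LTM 24 h against 8 h and 5489 for the difference of the drugs in that change. Median scaling moved the share of higher genes from 50.3% to 59.6% (2639 of 4428) for LTM 24 h against 8 h and from 50.2% to 44.8% (2395 of 5343) for LTM 24 h against control. In the fit of 9 arrays the counts of 0 became 416 for TFT 8 h, 158 for TFT 24 h, 4585 for LTM 8 h, 4256 for LTM against TFT at 8 h and 190 for TFT 24 h against 8 h. Genes called in the same direction went from 0 to 44 for TFT at both times, 3484 for LTM at both times, 258 for the drugs at 8 h and 68 at 24 h.

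Leaving out 1 array gave 0 to 1291 genes for LTM 8 h (highest without replicate 1), 3725 to 4672 for LTM 24 h, 3651 to 4648 for LTM against TFT at 24 h, 2767 to 4594 for LTM 24 h against 8 h and 1690 to 3416 for the difference of the drugs. The lowest count of the last 4 came without LTM 24 h replicate 2. LTM 24 h also moved to 3826 without control replicate 2, and the difference of the drugs to 2006 without TFT 24 h replicate 2. Where 1 array was left in a group it was assumed to vary like the other groups. List medians then ranged from -0.23 to 0.040 for DNA replication at TFT 24 h, and from -0.10 to 0.16 for mitosis in LTM against TFT at 8 h. For TFT 24 h against 8 h they ranged from -0.021 to 0.44 for p53 targets, -0.13 to 0.15 for DNA replication, -0.37 to 0.078 for histone genes, -0.066 to 0.12 for ER chaperones and -0.16 to 0.20 for heat shock.

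Directions reversed without the 3 arrays for CCNE1 (0.59) and H2AC6 (-1.11) at TFT 8 h and mitosis in LTM against TFT at 8 h (-0.14). For TFT 24 h against 8 h they reversed for histone genes (0.12), ER chaperones (-0.14), immediate early (0.070), snoRNA host (0.19) and heat shock (-0.21) lists. Other probes gave -0.020 for ATF4, 0.61 for ACTB and 0.17 for UQCRB at LTM 24 h.

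The replicate numbers were not shown to pair the arrays. At 8 h the same-numbered LTM and TFT arrays had deviations correlated at 0.69, -0.62 and 0.66, but these include 2 of the 3 doubted arrays and so show neither pairing nor its absence, and LTM at 24 h and 8 h gave 0.179 and 0.174. With the replicate number as a block the counts were 6160 for LTM 24 h, 6132 for LTM against TFT at 24 h, 5586 for LTM 24 h against 8 h and 3998 for the difference of the drugs, and 0 elsewhere. A crossed pairing gave 6166 for LTM 24 h (r = -0.116) and 6167 for LTM against TFT at 24 h (r = -0.247).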

Other observations

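The test of nonsense-mediated decay was chosen only after the result was seen.

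In the fit of 9 arrays, members of lists that did not pass camera also changed after LTM for 24 h. In that fit 3787 of all 12131 genes rose and 3914 fell, so changed members alone do not set a list apart. Of 26 ER chaperones, 16 fell and 5 rose (17 and 5 adjusted over the list alone; median -0.41, camera adjusted p = 0.0609), and of 26 cholesterol synthesis genes, 14 fell and 5 rose (15 and 5 adjusted over the list alone; median -0.52, camera adjusted p = 0.0669). Of 31 hypoxia and glycolysis genes, 17 fell and 7 rose (17 and 7 adjusted over the list alone; median -0.43, camera adjusted p = 0.306). The MAPK output list passed (12 of 21 rose and 3 fell, 12 and 3 adjusted over the list alone; median 0.52, camera adjusted p = 0.0346, adjusted p = 0.296 with an estimated correlation), with DUSP5 at 2.18, MAFF at 1.97 (another probe 0.76, adjusted p = 0.066) and PHLDA2 at -2.17.

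As a hypothesis, the higher snoRNA host transcripts after LTM may reflect a block of nonsense-mediated decay, a pathway that needs translation and is known to degrade several of these transcripts. The test made, that the list is higher at both times without the 3 arrays (camera adjusted p = 9.63e-05 at 8 h and 0.00293 at 24 h; adjusted p = 0.269 and 0.336 with an estimated correlation), restates the observation and lends the hypothesis no support. The hypothesis stays open, since a general rise of their transcription was not separated from slower decay.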
